A study of Homo sapiens with 16 samples.

How the data were processed

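RNA was measured by sequencing of poly(A)-selected libraries from HER2-positive breast cancer cells, 16 libraries in 8 groups of 2. Per the labels, 400 ng of total RNA went into each NEBNext Ultra II library, and the libraries were sequenced as paired reads of 150 bp on a NovaSeq instrument. The submitters' notes list CASAVA 1.8, cutadapt 1.16, STAR 2.7.3a, HTSeq 0.9.1, DESeq2, kallisto 0.46 and deepTools 3.5.0, with the hg19 genome. The deposited tables hold raw counts per gene from HTSeq, as whole numbers keyed by Ensembl gene identifier, and no normalised values from the authors were used. Neither the strand setting of the counting nor the annotation release is given in the sources used here. Reads of genes that overlap another gene on either strand may therefore be assigned to the wrong one, and values of such genes carry that doubt. Named genes with exons shared on the same strand are AMOTL2, ATRIP, BRCA1, C12orf57, CDC42EP2, CDK9, CPSF1, KLHL22, LAMB3, MCL1, MT-ATP6, NFE2L2, NMNAT1, NOP56, RPL18, RPL3, RPL8, RSRP1, TMPPE, ZNF296, ZNF324, ZNF649 and ZNF776. Exons on the opposite strand overlap those of BRCA1, C12orf57, CCDC77 (KDM5A), CCN2, CCNF, CDK13, CPSF1 (ADCK5), CPSF6 (MIR1279), DDIT4, DUSP6, EDIL3, ELL, ERRFI1, FADD, FANCA (ZNF276), FANCF (GAS2), ID2, IER2, IER5L, KLK10, KRT7-AS (KRT7), NFE2L2 (AGPS), PPP1R3D (FAM217B), RPL18 (SPHK2), RSRP1 (RHD and TMEM50A), STARD13, ZNF200, ZNF319 (USB1), ZNF324, ZNF649 and ZSWIM4. EID3, FOSB, GNE, PRR15L and ZNF486 lie within an intron of another gene.

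Each table listed 60234 gene identifiers, of which 39539 matched a current symbol and 27082 had no count in any library. Total counts ran from 13675303 to 18104368 per library. Gene types and genomic lengths came from the GENCODE annotation of GRCh38 by gene identifier, not from hg19, so no coordinates are given. Of the genes tested, 97.0% had a length.

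Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 8 groups, which left 15956 genes, 13046 of them protein coding. Libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, leaving 8 residual degrees of freedom and an estimated 6.82 prior degrees of freedom. The common coefficient of biological variation was 19.9%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and every adjusted p for a gene is from edgeR unless another tool is named. Fold changes are on the log2 scale with standard errors from the F statistic; intervals are 95% confidence intervals. Exact counting intervals and floors cover counting error only, not the spread between samples, and amplified reads are not independent molecules. Fits without 1 library that left a group 3 or fewer counts (ADAMTS15, ETAA1, RGS16, SMAD7 and SNORD3B-1) rest on few reads. Levels in CPM, normalised by TMM, are given as mean ± SD over the 2 libraries of a group. The labels mention no spike-in, so each value is relative to the other transcripts of its library. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

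The 11 comparisons were each inhibitor against DMSO in HCC1954, THZ531 against DMSO in SKBR3 and in sgMYC HCC1954, sgMYC against unedited HCC1954 in DMSO, the 3 inhibitors against each other in HCC1954, and the THZ531 response of SKBR3 or sgMYC HCC1954 minus that of HCC1954. The comparisons, tests, gene lists, first set of other settings and rule for naming genes were chosen before the data were examined. By that rule MYC and the kinases CDK12, CDK13, CDK9 and CDK7 are given. For each inhibitor against DMSO, the 8 largest rises and 8 largest falls among called genes are named, and for other comparisons 5 each way. These needed an average log2 CPM of at least 3, an approved symbol, and both libraries of one group above both of the other. Examples from a gene list come from its called members with the smallest adjusted p. Some genes that the rule names are not reported here.

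There were 23 gene lists: homologous recombination and Fanconi repair, DNA replication, mitosis, immediate early genes, MYC targets, p53 targets, replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, the nuclear-encoded respiratory chain, transcription elongation kinases and partners, 3-prime end processing, splicing regulators, survival and NF-kB targets, receptor tyrosine kinase feedback, the ERBB2 amplicon, TGF-beta and YAP targets, heat shock, the integrated stress response, the type I interferon response, luminal and basal epithelial markers, and stromal, immune and endothelial markers. Of the 30 histone genes 17 matched an identifier. The lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry.

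Overlaps of calls were compared with those of independent sets, and correlations across genes with 20 simulated sets in which no group differed from the HCC1954 DMSO libraries that 3 comparisons share. The calling was tested on simulated data with 200 genes changed. In a comparison of 2 groups, 2 of 67 genes changed by 1.5-fold, 33 of 67 changed by 2-fold and 58 of 66 changed by 4-fold were called, and 7.00% of calls were false. For the SKBR3 difference of responses the numbers were 0 of 67, 4 of 67 and 45 of 66, with 5.77% false calls. In that setting 1 gene was called with the wrong sign, and the limit for such calls was loosened after that 1 was seen. A list of 40 genes shifted by 1.5-fold was called and 0 of 22 unshifted lists were; none of these simulated settings had correlated genes.

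The other settings chosen then were the DESeq2 1.42.0 size factors in the edgeR fit, the DESeq2 Wald test, no filter on low counts, a stricter filter (at least 10 counts in each library of a group and an average log2 CPM of 1), a fit of only the groups compared, the replicate number as a block, and leaving out each library. Settings added after seeing the data were a fit without the NVP2 libraries, the NVP2 libraries summed as 1, and scaling to the 13 mitochondrially encoded mRNAs. The last of these rests on few transcripts, and whether mitochondrial mRNA itself stayed constant was not measured. Groups of zinc finger genes and gene types were also chosen after the data were seen.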

Results

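RNA was counted per gene in 16 libraries from human HER2-positive breast cancer cells, 8 groups of 2 libraries each. HCC1954 and SKBR3 are established lines with an amplified ERBB2 gene. HCC1954 cells received DMSO at 0.4% by volume, or 200 nM of THZ531, NVP2 or THZ1, for 4 h. SKBR3 cells, and HCC1954 cells whose genotype label names a CRISPR edit of MYC (sgMYC), received DMSO or THZ531. THZ531 is a covalent inhibitor of CDK12 and CDK13, NVP2 inhibits CDK9, and THZ1 is a covalent inhibitor of CDK7 that also binds CDK12 and CDK13. All of these kinases act on RNA polymerase II transcription.

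Total counts per library, replicate 1 then 2, were 17121233 and 15355986 for HCC1954 in DMSO, 16734022 and 15637519 with THZ531, 17425912 and 15457951 with NVP2, and 15832123 and 13675303 with THZ1. They were 18104368 and 15676643 for SKBR3 in DMSO and 15237363 and 16316881 with THZ531. For sgMYC HCC1954 they were 16203798 and 15340585 in DMSO and 16286723 and 16277374 with THZ531. The leading 2 principal components of log2 CPM held 70.3% and 14.9% of the variance. The coefficient of biological variation between replicates ran from 12.9% to 28.0% in 7 of the 8 groups and was 3.88% between the NVP2 libraries. In replicates 1 and 2, mitochondrially encoded mRNAs were 3.64% and 3.80% of counts in HCC1954 with NVP2 and 3.39% and 2.26% with THZ1. They were 3.35% and 2.17% for SKBR3 in DMSO and 4.83% and 2.97% with THZ531, and 1.71% and 1.19% for sgMYC cells in DMSO and 1.83% and 1.26% with THZ531. Values are relative to the rest of each library, so the split of calls into higher and lower depends on the scale. Scaling to the 13 mitochondrially encoded mRNAs in place of TMM, tried after the data were seen, moved the median log2 change of all genes by −1.05 for THZ531, −1.35 for NVP2 and −1.0 for THZ1 in HCC1954. It moved it by −0.79 for THZ531 in SKBR3, −0.30 for THZ531 in sgMYC cells and 0.17 for sgMYC against unedited cells. For THZ531 against NVP2 the shift was 0.30, for THZ1 against NVP2 0.35, and for the THZ531 response of SKBR3 or sgMYC cells minus that of HCC1954 0.26 and 0.74.

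The first comparison, THZ531 against DMSO in HCC1954, asks how inhibiting CDK12 and CDK13 alters mRNA levels. MYC (ENSG00000136997), a transcription factor that drives growth, rose from 244 ± 53 to 675 ± 136 CPM, a log2 change of 1.47 ± 0.27 (SE, n = 2 libraries per group, adjusted p = 0.00141). ID2, an inhibitor of basic helix-loop-helix factors, rose by 3.29 ± 0.47 (adjusted p = 0.000273), and RGS16, which dampens G protein signalling, rose by 3.20 ± 0.42 (adjusted p = 0.000128). ZC3H4, which restrains noncoding transcription, fell by 4.41 ± 0.32 (adjusted p = 2.77e-06), and FADD, the adaptor of death receptors, fell by 3.04 ± 0.22 (adjusted p = 2.77e-06). On the mitochondrial scale MYC stood at 0.39 ± 0.45 (adjusted p = 0.479).

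**Figure D1:**
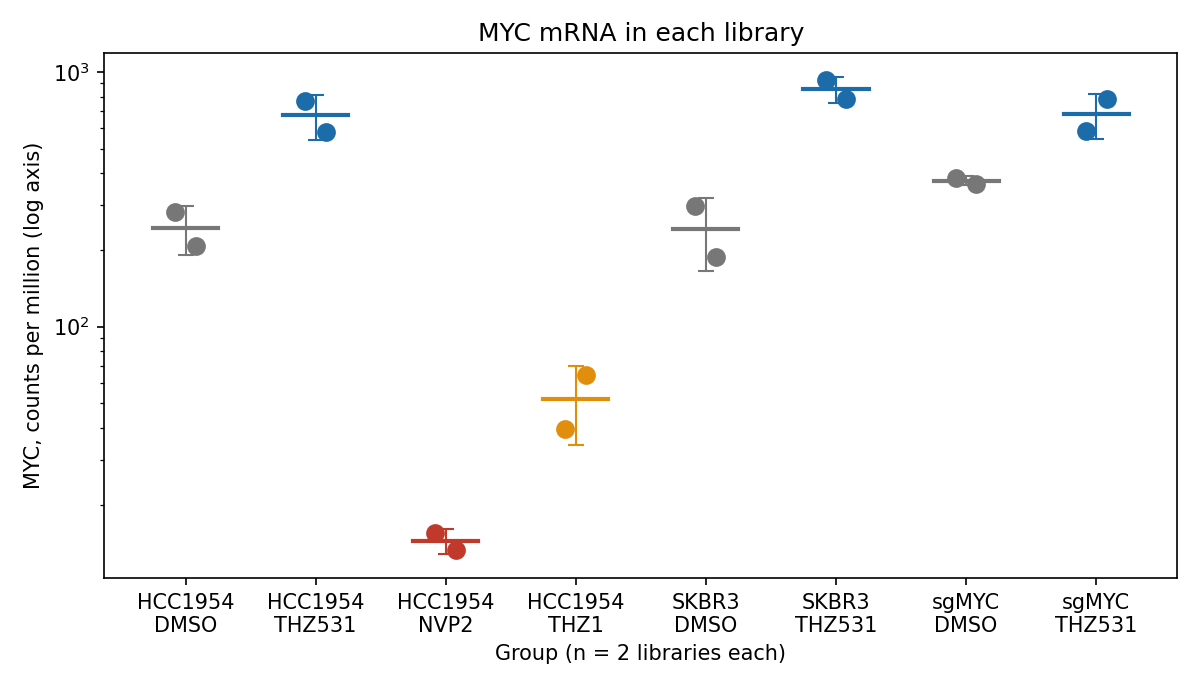
MYC level (CPM, vertical axis) in each of the 8 groups, where points are libraries, bars are means and whiskers are SD (n = 2). The mean was 675 CPM with THZ531 in HCC1954 against 244 in DMSO, and 14.4 with NVP2.

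Other large rises were EID3 (6.02 ± 0.54), MIR3648-2 (3.71 ± 0.64), the immediate early gene FOS (3.70 ± 0.72), the homeobox gene MNX1 (2.89 ± 0.34), RASD1 (2.31 ± 0.66, adjusted p = 0.0219) and TMPPE (2.16 ± 0.31). EID3 lies inside TXNRD1, TMPPE shares exons with GLB1, and MIR3648-2 lies in ribosomal DNA repeats, so the source of their reads is uncertain. Large falls were KRT7-AS (−4.09 ± 0.34), antisense to the keratin gene KRT7, the circadian factor TEF (−3.44 ± 0.36), ZNF526 (−3.38 ± 0.27), the focal adhesion gene TNS4 (−3.32 ± 0.30), the histamine receptor HRH1 (−3.02 ± 0.36) and the cyclin CCNF (−3.00 ± 0.27). Of the kinases, CDK9 (ENSG00000136807) fell by 0.80 ± 0.18 (adjusted p = 0.00675). CDK12 (ENSG00000167258) stood at −0.28 ± 0.19, CDK13 (ENSG00000065883) at 0.00 ± 0.16 and CDK7 (ENSG00000134058) at 0.02 ± 0.25, none called. The call of RASD1 ended without THZ531 replicate 2 (adjusted p = 0.08), DMSO replicate 1 (0.146) or DMSO replicate 2 (0.0527), and that of CDK9 ended without THZ531 replicate 1 (0.0508) or when only the 2 groups were fitted (0.0548). The calls of RASD1 (1.29, adjusted p = 0.154) and TMPPE (1.06, adjusted p = 0.0981) ended on the mitochondrial scale. HRH1 stood at −3.64 without THZ531 replicate 1 and MIR3648-2 at 4.56 without DMSO replicate 2.

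Of the 15956 genes tested, 1226 were higher and 2096 lower with THZ531, and 451 and 1450 of these by at least 2-fold. On the mitochondrial scale the split was 112 higher and 4847 lower, and 430 of the 1226 kept a change above 0. When only the 2 groups compared were fitted, 22.8% of calls were higher, against 36.9%. The split was 738 higher and 1365 lower without THZ531 replicate 2, 557 and 1372 without DMSO replicate 1, and 564 and 1545 without DMSO replicate 2. Median length was 28.3 kb in lower, 19.3 in higher and 29.4 in uncalled genes. Across genes (not independent replicates), its Spearman coefficient with change was −0.0802 (−0.0236 in sgMYC cells).

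Among 34 homologous recombination and Fanconi genes, which CDK12 loss is known to lower, 1 was higher and 11 lower (2 and 12 adjusted over the list alone), with a median of −0.30 (camera adjusted p = 0.00412, adjusted p = 0.581 with an estimated correlation). ATRIP, which carries the ATR kinase to damaged DNA, fell by 2.65 ± 0.40 and FANCF by 2.04 ± 0.31, while FANCA rose by 0.64 ± 0.17. ATRIP shares exons with TREX1. BRCA1 (−0.92 ± 0.25, adjusted p = 0.0159) and BRCA2 (−1.29 ± 0.20, adjusted p = 0.000491) were named after their values were seen. BRCA2 also fell with NVP2 and THZ1 (−2.02 and −1.82 or lower leaving out 1 library). BRCA1 was lowest with THZ531. ATRIP stood at −3.83 and −2.03 without THZ531 replicates 1 and 2. The call of BRCA1 ended without THZ531 replicate 2 or DMSO replicate 1, and that of FANCA without THZ531 replicate 1 or either DMSO library. With only the 2 groups fitted both ended (adjusted p = 0.103 and 0.0894), and FANCA stood at −0.46 on the mitochondrial scale.

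The higher lists all lost their direction or reached 0 on the mitochondrial scale. Immediate early genes had a median of 1.04, against −0.03 on the mitochondrial scale, with 8 of 21 higher and 0 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.000166). IER2, one of them, rose by 1.49 ± 0.26, or 0.46 on that scale, not called (adjusted p = 0.439). Replication-dependent histones had medians of 0.78 and −0.13 on the 2 scales, with 6 of 15 higher (6 adjusted over the list alone, camera adjusted p = 0.00207), among them H2BC21 (1.64 ± 0.25, or 0.62 on the mitochondrial scale, adjusted p = 0.314), a histone gene that also makes polyadenylated mRNA. Cytosolic ribosomal proteins had medians of 0.53 and −0.49, with 27 of 73 higher (41 adjusted over the list alone, camera adjusted p = 1.21e-10), and the nuclear-encoded respiratory chain 0.40 and −0.62, with 8 of 41 higher (8 adjusted over the list alone, camera adjusted p = 0.000154). The mitochondrially encoded mRNAs had a median of 1.14, with 10 of 13 higher (11 adjusted over the list alone, camera adjusted p = 0.000166). They were 4.03% and 2.13% of counts in THZ531 replicates 1 and 2, against 1.83% and 1.48% in DMSO. MT-CO2 (0.92) and MT-ND3 (0.72) lost their calls without THZ531 replicate 1 (0.58 and 0.50) or DMSO replicate 2. These calls also ended with only the 2 groups fitted (adjusted p = 0.102 and 0.107). Each of these 5 lists had an adjusted p = 0.581 with an estimated correlation.

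The other 17 lists were not called. Higher and lower members numbered 2 and 5 for DNA replication (camera adjusted p = 0.67), 1 and 1 for mitosis (0.425), 6 and 1 for MYC targets (0.077), 0 and 4 for p53 targets (0.719), 6 and 2 for transcription elongation (0.0994), 4 and 6 for 3-prime end processing (0.433) and 4 and 3 for splicing regulators (0.47). They numbered 2 and 5 for survival and NF-kB targets (0.365), 1 and 3 for receptor tyrosine kinase feedback (0.744), 0 and 1 for the ERBB2 amplicon (0.926), 5 and 3 for TGF-beta and YAP targets (0.65), 1 and 0 for heat shock (0.112), 1 and 2 for the integrated stress response (0.744) and 0 and 1 for the type I interferon response (0.744). The p53 list had a median of 0.13, a mean of −0.12 and a downward test. Luminal markers had 1 and 1 (0.738), basal markers 1 and 2 (0.401) and stromal, immune and endothelial markers 0 and 0 of 4 (0.744). The numbers adjusted over the list alone differed for MYC targets (8 and 3), elongation (6 and 3), 3-prime end processing (5 and 6), splicing regulators (6 and 3), survival and NF-kB targets (2 and 7), receptor tyrosine kinase feedback (1 and 4), TGF-beta and YAP targets (5 and 4), the integrated stress response (2 and 2) and basal markers (0 and 2). The cleavage factor gene CSTF1 fell by 1.67 ± 0.16.

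The NVP2 comparison in HCC1954 asks what inhibiting CDK9 does. MYC fell by 4.09 ± 0.30 (SE, n = 2 libraries per group, adjusted p = 1.1e-07), from 244 ± 53 to 14.4 ± 1.61 CPM. ID3 and ID1, inhibitors of basic helix-loop-helix factors, fell by 6.33 ± 0.53 and 5.52 ± 0.76, and the stress gene DDIT4 fell by 5.85 ± 0.55. FOS rose by 4.81 ± 0.74 (adjusted p = 0.000133) and EGR1, another immediate early gene, by 2.81 ± 0.59 (adjusted p = 0.00183). CDK9 itself fell by 1.24 ± 0.19, CDK13 fell by 1.93 ± 0.17, CDK12 fell by 0.71 ± 0.19 and CDK7 fell by 0.92 ± 0.25. The call of CDK12 ended without NVP2 replicate 1 (adjusted p = 0.0747), NVP2 replicate 2 (0.0806) or DMSO replicate 1 (0.074), and that of CDK7 without NVP2 replicate 1 (0.109) or DMSO replicate 1 (0.143). With the NVP2 libraries summed both ended (0.0788 for CDK12 and 0.0653 for CDK7). ID1 stood at −6.16 without DMSO replicate 1 and −4.36 without DMSO replicate 2, and ID3 at −5.60 without DMSO replicate 2.

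Further falls were ZNF92 (−5.87 ± 0.36), IER5L (−5.79 ± 0.56), ETAA1 (−5.64 ± 0.37), which activates ATR, the protease gene ADAMTS15 (−5.63 ± 0.51) and CDC42EP2 (−5.47 ± 0.37). Further rises were MIR3648-2 (6.86 ± 0.73), the multicopy SNORD3B-1 (5.86 ± 0.96), C12orf57 (2.50 ± 0.38), MT-ATP6 (1.60 ± 0.35), TMEM238 (1.54 ± 0.50, adjusted p = 0.0292) and MT-ND6 (1.52 ± 0.35, adjusted p = 0.00406). C12orf57 overlaps RNU7-1, and MT-ATP6 overlaps MT-ATP8 and MT-CO3. The call of TMEM238 ended without NVP2 replicate 1 (0.0888) or 2 (0.0958), or DMSO replicate 1 (0.156) or 2 (0.0636), and that of MT-ND6 without DMSO replicate 2 (0.051). The call of TMEM238 also ended with the NVP2 libraries summed (0.0859). Calls ended on the mitochondrial scale for C12orf57 (1.19, adjusted p = 0.0617), MT-ATP6 (0.28, adjusted p = 0.53), MT-ND6 (0.18, adjusted p = 0.699) and TMEM238 (0.15, adjusted p = 0.842). Without NVP2 replicate 1, ADAMTS15 stood at −6.25 and IER5L at −6.57. MIR3648-2 stood at 7.71 without DMSO replicate 2, and SNORD3B-1 at 5.15 and 7.20 without DMSO replicates 1 and 2.

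NVP2 raised 1504 genes and lowered 3494, 177 and 2763 of them by at least 2-fold. The split was 49 and 8778 on the mitochondrial scale, where 126 of the 1504 stayed above 0. The share higher was 30.1%, against 41.5% with DESeq2 size factors, which moved the median of all genes by 0.11, 42.2% by the DESeq2 Wald test, 45.2% when only these groups were fitted and 17.0% when the NVP2 libraries were summed. Higher and lower calls numbered 463 and 2483 without NVP2 replicate 1, 530 and 2511 without NVP2 replicate 2, and 495 and 2878 without DMSO replicate 2.

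TGF-beta and YAP targets had a median of −2.77, with 0 of 13 higher and 10 lower (0 and 10 adjusted over the list alone, camera adjusted p = 2.87e-09, adjusted p = 0.00376 with an estimated correlation). SMAD7, which feeds back on TGF-beta signalling, fell by 5.92 ± 0.35 and stood at −6.60 without NVP2 replicate 1. Receptor tyrosine kinase feedback genes had a median of −2.23, with 12 of 15 lower (12 adjusted over the list alone, camera adjusted p = 7.02e-11, adjusted p = 0.0415 with an estimated correlation), among them the ERK phosphatases DUSP4 (−3.86 ± 0.18) and DUSP6 (−4.49 ± 0.34). Survival and NF-kB targets had a median of −1.24, with 12 of 17 lower (13 adjusted over the list alone, camera adjusted p = 1.15e-05, adjusted p = 0.0186 with an estimated correlation), among them MCL1 (−3.49 ± 0.19), which blocks apoptosis.

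Called only at the preset correlation were immediate early genes, with 3 higher and 13 lower (5 and 13 adjusted over the list alone) and a median of −2.17 (camera adjusted p = 0.000539 and 0.427). The integrated stress response had 2 higher and 9 lower (3 and 9 adjusted over the list alone, median −1.62, camera adjusted p = 0.00114 and 0.0695), with the stress gene SESN2 at −5.17 ± 0.40. Targets of p53 had 2 and 11 (2 and 11 adjusted over the list alone, median −0.92, camera adjusted p = 0.00546 and 0.061). Elongation genes had 2 and 13 (2 and 13 adjusted over the list alone, median −0.41, camera adjusted p = 0.00554 and 0.339), with CCNT1, the cyclin of CDK9, at −2.47 ± 0.18. The second p of each pair is with an estimated correlation.

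Higher lists under NVP2 reversed on the mitochondrial scale: DNA replication from a median of 0.34 to −1.01 (12 higher and 3 lower, and 13 and 3 adjusted over the list alone, camera adjusted p = 0.00461 and 0.446) and histones from 0.48 to −0.87 (2 higher, and 0 adjusted over the list alone, camera adjusted p = 0.0224 and 0.427). Ribosomal proteins went from 0.53 to −0.84 (36 higher, and 39 adjusted over the list alone, camera adjusted p = 1.81e-09 and 0.427), and the respiratory chain from 0.64 to −0.72 (22 higher, and 28 adjusted over the list alone, camera adjusted p = 5.91e-08 and 0.393). The mitochondrially encoded mRNAs had a median of 1.37, with 9 of 13 higher (12 adjusted over the list alone, camera adjusted p = 1.54e-05 and 0.393). The repair list had a median of 0.10, a mean of −0.55 and a downward test (camera adjusted p = 0.224), with 2 higher and 13 lower (2 and 14 adjusted over the list alone). The second p of each pair is with an estimated correlation.

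For THZ1 in HCC1954 the question is the effect of inhibiting CDK7. MYC fell by 2.23 ± 0.28 (SE, n = 2 libraries per group, adjusted p = 2.69e-05) to 52.2 ± 17.9 CPM. FADD fell by 5.18 ± 0.26 and ETAA1 fell by 5.68 ± 0.38, while FOS rose by 3.60 ± 0.72 (adjusted p = 0.00149) and ARC, an immediate early gene of neurons, by 5.99 ± 1.0 (adjusted p = 0.000371). CDK13 fell by 0.91 ± 0.16 and CDK9 fell by 1.06 ± 0.19; CDK12 stood at −0.50 ± 0.19 (adjusted p = 0.0599) and CDK7 at −0.13 (adjusted p = 0.729), neither called. Without THZ1 replicate 2 the call of FOS ended (1.47, adjusted p = 0.0548); without THZ1 replicate 1 it stood at 4.43. ARC stood at 3.58 without THZ1 replicate 2, 6.86 without replicate 1, 7.38 without DMSO replicate 1 and 5.33 without DMSO replicate 2, and ETAA1 at −6.37 without THZ1 replicate 2.

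The remaining large falls were ZNF526 (−5.07 ± 0.31), the phosphatase subunit gene PPP1R3D (−4.89 ± 0.29), ZNF319 (−4.84 ± 0.32), ADAMTS15 (−4.56 ± 0.47), ZNF324 (−4.48 ± 0.38) and MOCS3 (−4.44 ± 0.25), needed for the molybdenum cofactor. The remaining large rises were MIR3648-2 (6.62 ± 0.72), the collagenase MMP13 (3.10 ± 0.67, adjusted p = 0.00256), FOSB (2.36 ± 0.52, adjusted p = 0.00298), EGR1 (2.25 ± 0.58, adjusted p = 0.00793), the creatine kinase CKB (1.87 ± 0.36) and EDIL3 (1.83 ± 0.36). Calls ended without THZ1 replicate 2 for MMP13 (0.67, adjusted p = 0.21), FOSB (0.77, adjusted p = 0.135) and EGR1 (0.47, adjusted p = 0.462), and for EGR1 also without DMSO replicate 2 (1.87, adjusted p = 0.0782). Without THZ1 replicate 1 these stood at 3.96, 3.11 and 3.03, ADAMTS15 at −5.57 and PPP1R3D at −5.52. CKB stood at 1.2 and MIR3648-2 at 5.91 without THZ1 replicate 2, and MIR3648-2 at 7.47 without DMSO replicate 2. Mitochondrial scaling ended the calls of CKB (1.0, adjusted p = 0.119), EDIL3 (0.93, adjusted p = 0.151) and EGR1 (1.48, adjusted p = 0.071), and that of EGR1 also ended when only the 2 groups were fitted (0.0674).

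THZ1 raised 1984 genes and lowered 3176 (361 and 2461 by at least 2-fold), against 53 and 5435 on the mitochondrial scale, where 410 of the 1984 stayed above 0. Without THZ1 replicate 2 the split was 1110 and 2604, without DMSO replicate 1 1293 and 2603, and without DMSO replicate 2 813 and 2623. TGF-beta and YAP targets had a median of −1.94, with 0 higher and 8 lower of 13 (1 and 9 adjusted over the list alone, camera adjusted p = 5.54e-06, adjusted p = 0.0192 with an estimated correlation). AMOTL2, which restrains YAP, fell by 3.42 ± 0.24. Not held with an estimated correlation, whose p stands second, were receptor tyrosine kinase feedback (1 and 10; 1 and 11 adjusted over the list alone, median −1.27, camera adjusted p = 4.17e-06 and 0.206), survival and NF-kB targets (0 and 10; 0 and 10 adjusted over the list alone, median −0.72, camera adjusted p = 0.000715 and 0.07) and the integrated stress response (3 and 7; 3 and 8 adjusted over the list alone, median −1.30, camera adjusted p = 0.0429 and 0.271). DUSP4 fell by 2.98 ± 0.17 and MCL1 fell by 1.77 ± 0.17. Immediate early genes had 5 higher and 11 lower (median −1.04, camera adjusted p = 0.0701), so that list was not called.

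Under THZ1 the higher lists again reversed on the mitochondrial scale. Ribosomal protein medians were 0.71 and −0.31 on the respective scales (50 of 73 higher, and 55 adjusted over the list alone, camera adjusted p = 1.45e-14 and 0.401), and respiratory chain medians 0.77 and −0.23 (28 of 41 higher, and 35 adjusted over the list alone, camera adjusted p = 6.41e-11 and 0.271). DNA replication had 0.34 and −0.66 (8 higher and 3 lower, and 8 and 3 adjusted over the list alone, camera adjusted p = 0.0429 and 0.684) and histones 0.55 and −0.46 (5 higher, and 7 adjusted over the list alone, camera adjusted p = 0.0192 and 0.492). Mitochondrially encoded mRNAs had a median of 1.03 (7 of 13 higher, and 12 adjusted over the list alone, camera adjusted p = 0.000409 and 0.492). The second p of each pair is with an estimated correlation.

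**Figure D2:**
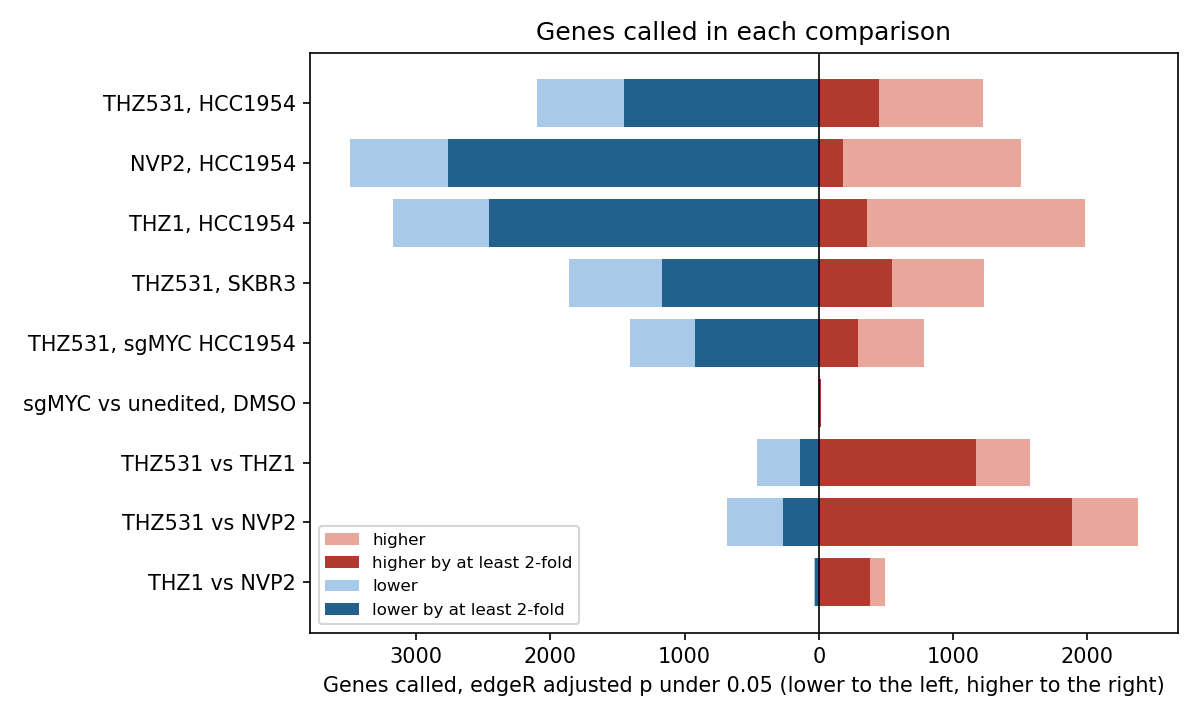
Number of genes called higher or lower (horizontal bars, adjusted p under 0.05) in each comparison, out of 15956 tested. THZ531 in HCC1954 gave 1226 higher and 2096 lower, NVP2 1504 and 3494, and THZ1 1984 and 3176; on the mitochondrial scale higher calls fell to 112, 49 and 53.

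Across the 3 inhibitors in HCC1954, 386 genes were higher and 1425 lower with each. THZ531 and NVP2 shared 429 higher and 1502 lower calls, where independent sets of those sizes would share 116 and 459. THZ531 and THZ1 shared 573 and 1598 (152 and 417 for independent sets), and NVP2 and THZ1 1157 and 2750 (187 and 695). The comparisons used the same DMSO libraries. Covariances of log2 changes across genes were 0.670, 0.894 and 1.24 for these pairs, against at most 0.161, 0.164 and 0.158 in simulated sets with no change. The Pearson coefficients, 0.454, 0.645 and 0.747, had simulated means of 0.474, 0.465 and 0.466, and at most 1 shared call arose in any simulated set.

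A set of 110 genes, defined after the data were seen, was higher with THZ531, lower with NVP2 and with THZ1, and different in both direct tests. The homeobox gene DLX2 had the largest rise among them, 2.53 with THZ531 against −2.14 with THZ1, and had 0 and 1 counts with NVP2. Median changes of the set were 0.95 with THZ531, −2.77 with NVP2 and −1.20 with THZ1. In cells not used to choose them, the medians with THZ531 were 0.85 in SKBR3 (73 called higher) and 0.81 in sgMYC cells (71 called higher). On the mitochondrial scale 49 of the 110 kept all 3 directions. In all, 210 genes were higher with THZ531 and lower with NVP2, and 4 the reverse, where independent sets would give 268 and 198, and 113 were higher with THZ531 and lower with THZ1, and 1 the reverse (244 and 261 for independent sets).

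**Figure D3:**
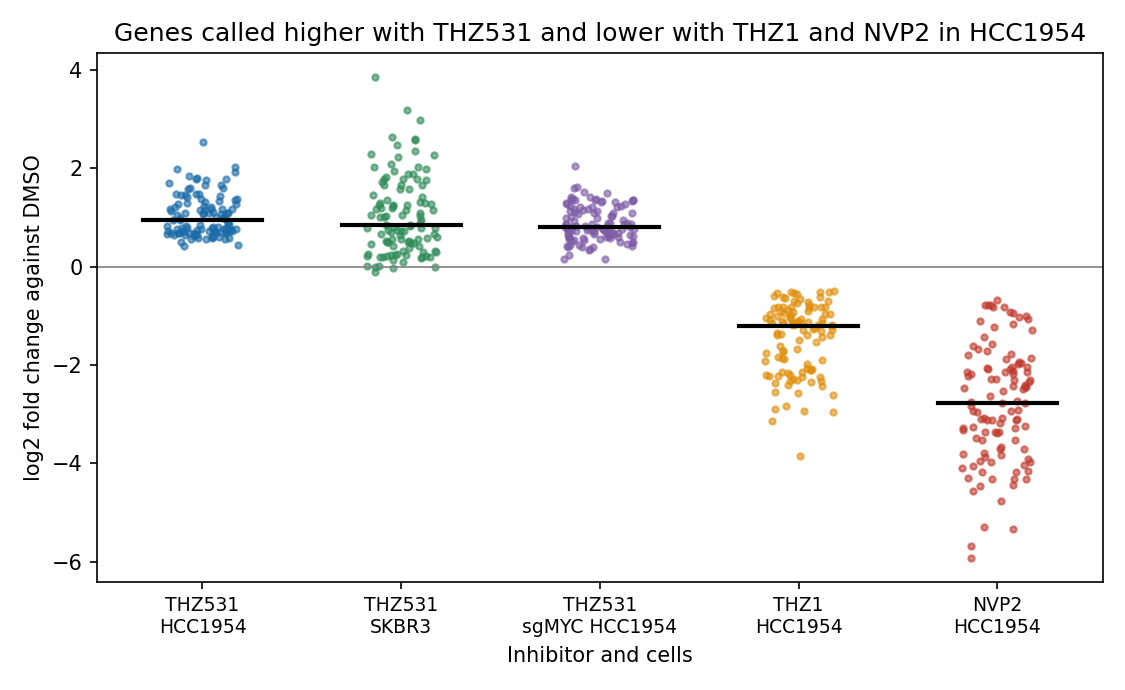
Log2 change against DMSO (vertical axis) of the 110 genes higher with THZ531 and lower with NVP2 and THZ1 in HCC1954, where points are genes and lines are medians. Medians were 0.95, −2.77 and −1.20 in the groups used to choose them, and 0.85 in SKBR3 and 0.81 in sgMYC cells with THZ531; on the mitochondrial scale 49 kept all 3 directions.

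THZ531 in SKBR3 asks whether the CDK12 response holds in another HER2-positive line. MYC rose by 1.82 ± 0.27 (SE, n = 2 libraries per group, adjusted p = 0.00043), from 242 ± 76.6 to 853 ± 102 CPM, and stood at 1.07 on the mitochondrial scale (adjusted p = 0.0981). SGK1, a kinase downstream of PI3K, rose by 3.86 ± 0.43 and SNAI1, a repressor of E-cadherin, by 2.98 ± 0.31. ZNF526 fell by 3.31 ± 0.26 and TFAP4, a MYC-regulated factor, fell by 2.91 ± 0.27. CDK12, a neighbour of ERBB2 that averaged 1723 CPM in SKBR3 in DMSO against 119 in HCC1954, fell by 0.73 ± 0.19 (adjusted p = 0.0144) and CDK9 fell by 0.81 ± 0.19 (adjusted p = 0.00734); CDK13 stood at −0.20 and CDK7 at 0.12, neither called. The call of CDK12 ended without THZ531 replicate 2 (adjusted p = 0.168) or DMSO replicate 1 (0.0958), and that of CDK9 without THZ531 replicate 2 (0.0513) or DMSO replicate 2 (0.0805).

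Other rises in SKBR3 were MIR3648-2 (5.86 ± 0.74), ARC (3.77 ± 0.82, adjusted p = 0.00551), FOS (3.59 ± 0.72), H2BC21 (3.20 ± 0.28), the peptide hormone ADM (3.18 ± 0.31) and RGS16 (2.92 ± 0.39). Other falls were PRR15L (−4.00 ± 0.59), the mediator subunit MED9 (−2.93 ± 0.29), and the zinc finger genes ZNF486 (−3.44 ± 0.46), ZNF776 (−3.16 ± 0.35), ZNF200 (−2.90 ± 0.38) and ZNF649 (−2.88 ± 0.41). The call of ARC ended without DMSO replicate 2 (3.53, adjusted p = 0.0611). ADM stood at 3.88 without DMSO replicate 1, MIR3648-2 at 6.73 without DMSO replicate 2 and ZNF486 at −4.04 without THZ531 replicate 2. In total 1231 genes were higher and 1861 lower (545 and 1166 by at least 2-fold), or 155 and 2742 on the mitochondrial scale, where 694 of the 1231 stayed above 0. Higher and lower calls were 785 and 1283 without THZ531 replicate 1, 550 and 848 without THZ531 replicate 2, 484 and 1030 without DMSO replicate 1, and 312 and 1010 without DMSO replicate 2. Genes called higher had a median length of 9.41 kb, those called lower 31.1 kb and uncalled genes 30.1 kb.

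**Figure D4:**
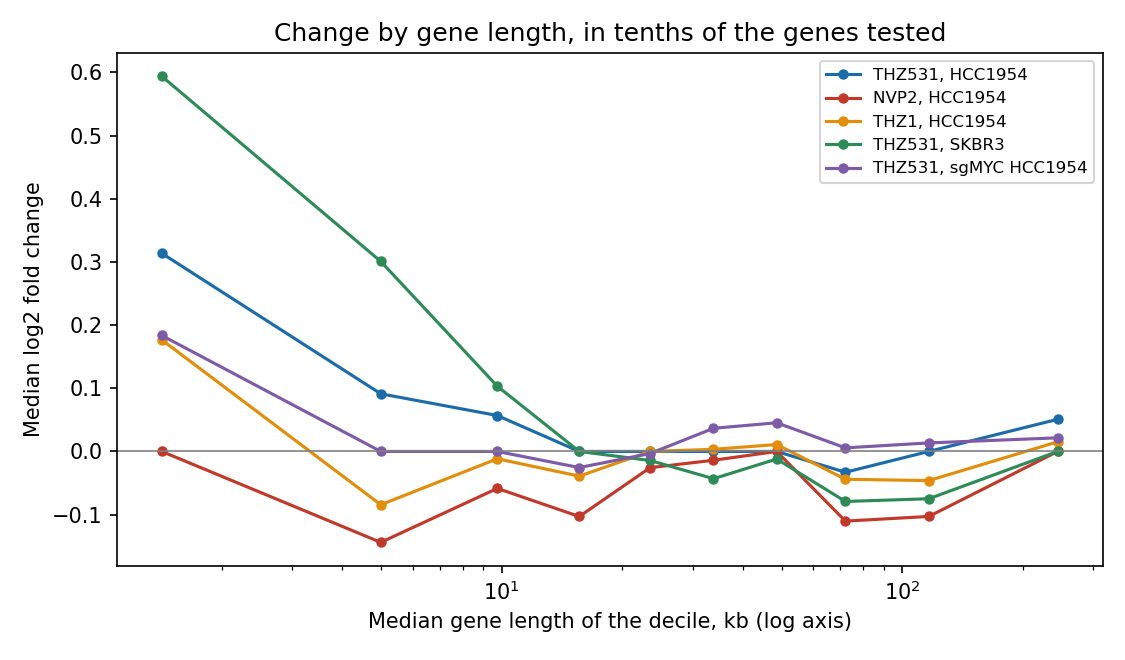
Median log2 change (vertical axis) of genes in 10 groups of equal size by genomic length, against the median length of each group in kb (log scale), for the 5 comparisons with DMSO. The group of shortest genes, at 1.42 kb, had medians of 0.31 in HCC1954 and 0.59 in SKBR3 with THZ531.

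Immediate early genes in SKBR3 had a median of 1.82, or 1.07 on the mitochondrial scale, with 13 of 21 higher and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 9.72e-14 and 0.26). ZFP36, which degrades mRNA, rose by 2.78 ± 0.28 and JUN by 2.76 ± 0.33. TGF-beta and YAP targets had a median of 1.24 (5 higher and 3 lower, and 7 and 3 adjusted over the list alone, camera adjusted p = 0.018 and 0.26), with CCN1, a YAP target, at 2.59 ± 0.25. The repair list had 0 higher and 9 lower (0 and 10 adjusted over the list alone, median −0.20, camera adjusted p = 0.0089 and 0.503), among them EXO1 (−1.47 ± 0.22) and XRCC2 (−1.66 ± 0.28). Histones had a median of 0.86 (4 higher, and 4 adjusted over the list alone, camera adjusted p = 0.000172 and 0.375). The second p of each pair is with an estimated correlation.

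Medians of further SKBR3 lists were above 0 by TMM and below it on the mitochondrial scale. They were 0.66 and −0.10 for ribosomal proteins (45 of 73 higher, and 62 adjusted over the list alone, camera adjusted p = 2.4e-16 and 0.375) and 0.58 and −0.18 for the respiratory chain (15 of 41 higher, and 21 adjusted over the list alone, camera adjusted p = 3.05e-08 and 0.375). They were 0.71 and −0.06 for heat shock genes (5 of 10 higher, and 7 adjusted over the list alone, camera adjusted p = 0.000884 and 0.26) and 0.32 and −0.46 for MYC targets (5 higher and 2 lower, and 8 and 2 adjusted over the list alone, camera adjusted p = 0.018 and 0.54). The chaperone HSP90AB1 rose by 0.87 ± 0.17 and NOP56, a nucleolar MYC target, by 1.49 ± 0.22, and on the mitochondrial scale neither was called (0.10, adjusted p = 0.904, and 0.74, adjusted p = 0.231). Mitochondrially encoded mRNAs had 0.77 and −0.01 (0 of 13 called, and 7 higher adjusted over the list alone, camera adjusted p = 0.00359 and 0.513). The second p of each pair is with an estimated correlation.

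THZ531 in sgMYC HCC1954 asks about the same response where MYC carries a CRISPR edit. MYC mRNA rose by 0.87 ± 0.26 (SE, n = 2 libraries per group, adjusted p = 0.0404), from 373 ± 15.0 to 681 ± 138 CPM, and stood at 0.61 on the mitochondrial scale (adjusted p = 0.652). ID2 rose by 3.45 ± 0.46 and FOS by 3.91 ± 0.73, while ZC3H4 fell by 3.32 ± 0.30 and TNS4 fell by 3.01 ± 0.29. CDK12 stood at −0.02 ± 0.19, CDK13 at −0.09, CDK9 at −0.53 ± 0.18 (adjusted p = 0.0702) and CDK7 at 0.48, none called. The call of MYC ended without THZ531 replicate 1 (adjusted p = 0.0544) or 2 (0.272), DMSO replicate 1 (0.146) or 2 (0.159), or the NVP2 libraries (0.0587). FOS stood at 4.52 and 2.85 without THZ531 replicates 1 and 2, and ID2 at 2.50 without THZ531 replicate 2.

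More rises in sgMYC cells were EID3 (5.18 ± 0.53), MIR3648-2 (4.71 ± 0.67), RGS16 (3.05 ± 0.42), ANKRD36C (2.12 ± 0.46, adjusted p = 0.00788), the Notch regulator NRARP (1.99 ± 0.40, adjusted p = 0.00458) and the chemokine CCL2 (1.90 ± 0.41, adjusted p = 0.00682). More falls were ZSWIM4 (−2.79 ± 0.29), HRH1 (−2.78 ± 0.35), ZNF623 (−2.77 ± 0.32), the transcription repressor ZHX2 (−2.73 ± 0.24), KRCC1 (−2.55 ± 0.30) and STARD13 (−2.51 ± 0.30). Without THZ531 replicate 2 or DMSO replicate 1 the calls ended for ANKRD36C (1.53, adjusted p = 0.0988; 0.0959), CCL2 (0.0908; 0.0818) and NRARP (1.11, adjusted p = 0.0924; 0.0575). These calls also ended on the mitochondrial scale (ANKRD36C 1.81, adjusted p = 0.112; CCL2 1.63, adjusted p = 0.115; NRARP 1.77, adjusted p = 0.0818). RGS16 stood at 2.37 without THZ531 replicate 2. MIR3648-2 stood at 5.32 and 3.62 without THZ531 replicates 1 and 2, and at 5.45 without DMSO replicate 2. In total 784 genes were higher and 1406 lower (289 and 921 by at least 2-fold), or 67 and 454 on the mitochondrial scale, where all 784 stayed above 0 and 66 of them were still called. Higher and lower genes were 320 and 786 without THZ531 replicate 1, 197 and 438 without THZ531 replicate 2, 203 and 706 without DMSO replicate 1, and 448 and 872 without DMSO replicate 2.

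In sgMYC cells 4 lists were called, each with an adjusted p = 0.777 with an estimated correlation, and each with a median above 0 on both scales. Immediate early genes had a median of 0.87 (8 of 21 higher, and 9 adjusted over the list alone, camera adjusted p = 0.000378) and histones 0.51 (3 of 15 higher, and 3 adjusted over the list alone, camera adjusted p = 0.0106). Ribosomal proteins had 0.38 (1 of 73 higher, and 0 adjusted over the list alone, camera adjusted p = 1.68e-06) and the respiratory chain 0.34 (4 of 41 higher, and 2 adjusted over the list alone, camera adjusted p = 0.000175). IER2 rose by 1.14 ± 0.26, and its call ended without THZ531 replicate 2 (adjusted p = 0.0639), DMSO replicate 1 (0.0506) or DMSO replicate 2 (0.0744). The splicing kinase CLK1 rose by 1.13 ± 0.17, and CSTF1 fell by 1.07 ± 0.15. None of these genes was called on the mitochondrial scale (IER2 0.86, adjusted p = 0.455; CLK1 0.81, adjusted p = 0.457; CSTF1 −1.39, adjusted p = 0.0767).

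With THZ531 in all 3 cell populations, 315 genes were higher and 859 lower. HCC1954 and SKBR3 shared 671 higher and 1328 lower calls, where independent sets would share 94.6 and 244, and 3 and 3 genes were called in opposite directions. HCC1954 and sgMYC HCC1954 shared 514 and 1207 (60.2 and 185 for independent sets), with 0 in opposite directions. Pearson coefficients across genes were 0.594 and 0.645.

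**Figure D5:**
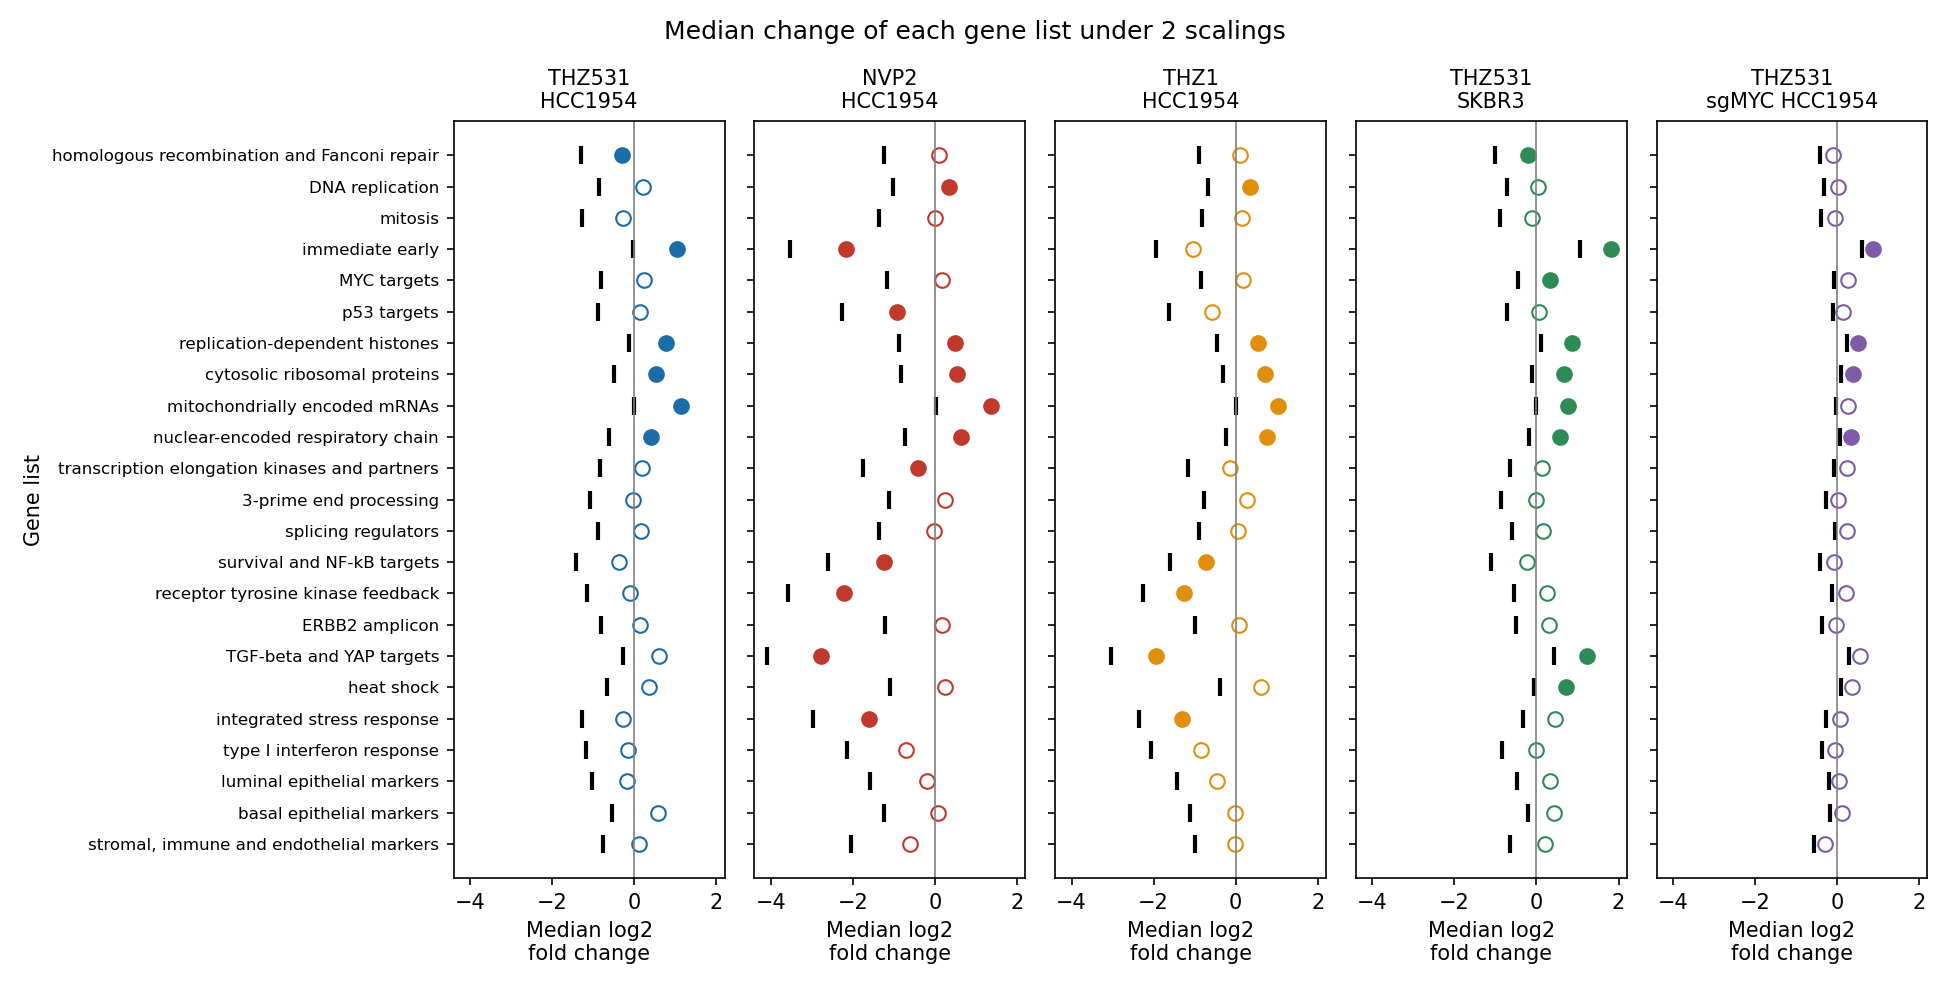
Median log2 change of each gene list (horizontal axis) in the 5 comparisons with DMSO, 1 per panel, where filled circles had a camera adjusted p under 0.05, open circles did not, and ticks are medians on the mitochondrial scale. Immediate early genes lay at 1.04 with THZ531 and −2.17 with NVP2 in HCC1954, and the former was −0.03 on the mitochondrial scale.

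The comparison of sgMYC with unedited HCC1954 in DMSO sets the edited population beside the unedited one, and differences of clone, selection or culture are not separated from the edit. IL1B, an inflammatory cytokine, was higher by 4.27 ± 0.52 (SE, n = 2 libraries per group, adjusted p = 0.00481), as were the protease KLK10 (2.12 ± 0.23, adjusted p = 0.00481) and the keratin KRT16 (1.83 ± 0.23, adjusted p = 0.00481). The fatty acid desaturase FADS3 (1.72 ± 0.30, adjusted p = 0.0437), the cytokine IL24 (1.48 ± 0.25, adjusted p = 0.0425) and the laminin LAMB3 (1.20 ± 0.20, adjusted p = 0.0419) were also higher. MYC mRNA stood at 0.61 ± 0.26 (0.05 to 1.17, adjusted p = 0.418), CDK12 at −0.13, CDK13 at −0.04, CDK9 at 0.13 and CDK7 at −0.19, none called. By edgeR 16 genes were higher and 0 lower, with 1760 at an unadjusted p under 0.05, while the DESeq2 Wald test called 164 higher and 21 lower, edgeR without a filter 303 and 70, and edgeR with only the 2 groups fitted 44 and 4. Without unedited replicate 1 or 2, or sgMYC replicate 1 or 2, 0, 1, 3 and 8 genes were called. Each of the named calls ended in at least 1 of these. Adjusted p without unedited replicate 1 was 0.0924 for IL1B and KLK10, 0.16 for KRT16, 0.351 for FADS3, and 0.235 for IL24 and LAMB3. Without unedited replicate 2 it was 0.099 for IL1B, 0.0534 for KRT16, 0.149 for FADS3, 0.159 for IL24 and 0.153 for LAMB3. Without sgMYC replicate 1 it was 0.0646 for IL1B, 0.0831 for KRT16, 0.371 for FADS3 and LAMB3, and 0.22 for IL24, and without sgMYC replicate 2 it was 0.0592 for FADS3 and 0.121 for IL24. On the mitochondrial scale it was 0.116 for KLK10, 0.187 for KRT16, 0.258 for FADS3 and IL24, and 0.553 for LAMB3. With the NVP2 libraries left out it was 0.0852 for FADS3, IL24 and LAMB3, and with only the 2 groups fitted 0.0713 for LAMB3.

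Basal epithelial markers were higher in sgMYC cells, with a median of 0.52 and 3 of 16 called (7 adjusted over the list alone, camera adjusted p = 5.03e-07, adjusted p = 0.296 with an estimated correlation). MYC targets had a median of −0.35 (camera adjusted p = 4.72e-05, adjusted p = 0.296 with an estimated correlation), the repair list −0.34 (camera adjusted p = 5.7e-06, adjusted p = 0.262 with an estimated correlation), DNA replication −0.28 (camera adjusted p = 1.56e-05), mitosis −0.24 (camera adjusted p = 0.000477) and 3-prime end processing −0.24 (camera adjusted p = 0.00449, adjusted p = 0.211 with an estimated correlation). The interferon list stood at 0.64 (camera adjusted p = 0.000128), histones at 0.36 (0.000477), receptor tyrosine kinase feedback at 0.26 (0.0123), TGF-beta and YAP targets at 0.25 (0.0176), survival and NF-kB targets at 0.20 (0.00684) and immediate early genes at 0.16 (0.0463). None of these 12 lists was called with an estimated correlation. The lower medians moved toward 0 on the mitochondrial scale, to −0.14 for MYC targets, −0.14 for the repair list, −0.09 for DNA replication, −0.05 for mitosis and −0.08 for 3-prime end processing. The higher ones moved to 0.60 for basal markers, 0.82 for interferon, 0.56 for histones, 0.44 for receptor feedback, 0.48 for TGF-beta and YAP targets, 0.35 for survival targets and 0.41 for immediate early genes.

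THZ531 and THZ1 share a chloro-indolyl-pyrimidine core and a dimethylaminobutenamide group that reacts with cysteine; THZ531 has an aminopiperidine where THZ1 has a diaminobenzene ring. At 200 nM for 4 h in HCC1954, MYC was higher with THZ531 than with THZ1 by 3.70 ± 0.29 (SE, n = 2 libraries per group, adjusted p = 1.37e-06). ADM was higher by 4.55 ± 0.31, ZNF296 by 4.94 ± 0.28 and CITED4, a transcription co-regulator, by 4.43 ± 0.56, while NMNAT1, which makes NAD, stood at −2.13 ± 0.35 and GNE, a sialic acid enzyme, at −1.90 ± 0.34. CDK13 was higher by 0.91 ± 0.16 (adjusted p = 0.00143). Its call ended when only the 2 groups were fitted (0.0856) and on the mitochondrial scale (0.83, adjusted p = 0.53), and that of GNE ended on that scale (0.0538). CDK12 (0.22, −0.19 to 0.63), CDK9 (0.26, −0.13 to 0.66) and CDK7 (0.15, −0.38 to 0.68) were not called.

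The antagonist of bone morphogenetic proteins NOG had 321 and 214 counts with THZ531 and 13 and 0 with THZ1, a ratio of 37.4 (exact interval for counting error only, 21.7 to 70.7), and was at least 73.6-fold higher than in THZ1 replicate 2 at a floor of 3 counts. CYP1A1, which oxidises aryl hydrocarbons, was higher by 4.59 ± 0.75, or 3.22 and 5.26 without THZ531 replicates 1 and 2 and 5.40 without THZ1 replicate 2. The fitted value of NOG was 5.22 ± 0.60, and 4.32 without THZ1 replicate 2; without THZ1 replicate 1 the library left had 0 counts, so no fold is given. Lower with THZ531 were MIR3648-2 (−2.91 ± 0.59, or −2.20 without THZ1 replicate 2), the death ligand TNFSF10 (−1.65 ± 0.40, adjusted p = 0.0131) and the interferon-induced SLFN5 (−1.58 ± 0.39, adjusted p = 0.0143). The call of TNFSF10 ended without THZ531 replicate 1 (0.108) or THZ1 replicate 2 (0.174), and it stood at −2.36 without THZ531 replicate 2. That of SLFN5 ended without THZ531 replicate 1 (0.11) or THZ1 replicate 2 (−0.70, adjusted p = 0.305). Both ended when only the 2 groups were fitted (0.112 for TNFSF10 and 0.129 for SLFN5) and on the mitochondrial scale (0.187 and 0.138).

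Of all genes 1571 were higher with THZ531 and 463 lower (1169 and 143 by at least 2-fold), or 424 and 6 on the mitochondrial scale, and 97.4% of calls were higher when only these groups were fitted, against 77.2%. The split was 1033 and 219 without THZ531 replicate 1 and 1014 and 67 without THZ1 replicate 2. TGF-beta and YAP targets had a median of 1.90 (7 of 13 higher, and 7 adjusted over the list alone, camera adjusted p = 1.09e-11, adjusted p = 0.00147 with an estimated correlation), with CCN1 higher by 3.94 ± 0.26. Immediate early genes had 1.62 (13 of 21 higher, and 14 adjusted over the list alone, camera adjusted p = 1.09e-11, adjusted p = 0.161 with an estimated correlation) and receptor tyrosine kinase feedback 1.14 (8 of 15; 9 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.15e-08, adjusted p = 0.0938 with an estimated correlation). Survival and NF-kB targets had 0.39 (camera adjusted p = 0.00146, adjusted p = 0.0909 with an estimated correlation), p53 targets 0.47 (0.0327, and 0.161 with an estimated correlation), elongation genes 0.27 (0.00132 and 0.167) and the integrated stress response 0.57 (0.0148 and 0.161). Lower medians were −0.33 for mitosis (0.00132, and 0.378 with an estimated correlation), −0.13 for DNA replication (0.0327 and 0.701), −0.18 for ribosomal proteins (0.00156 and 0.787) and −0.42 for the respiratory chain (2.42e-05 and 0.459). MCL1 was higher by 1.53 ± 0.17 (1.46 on the mitochondrial scale, not called, adjusted p = 0.104) and the elongation factor gene ELL by 1.82 ± 0.19.

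THZ531 against NVP2, a non-covalent inhibitor of another structure, sets the CDK12 response beside that of CDK9. MYC was higher with THZ531 by 5.55 ± 0.32 (SE, n = 2 libraries per group, adjusted p = 1.01e-08). SMAD7 was higher by 6.80 ± 0.35, ID3 by 6.94 ± 0.54 and IER5L by 7.68 ± 0.58. RGS16 had 444 and 479 counts with THZ531 and 0 and 3 with NVP2, a ratio of 332 (exact interval for counting error only, 113 to 1614), and was at least 177-fold higher than in NVP2 replicate 1 at a floor of 3 counts. The fitted value of RGS16 was 8.26 ± 0.66, and 7.23 without NVP2 replicate 1; without NVP2 replicate 2 the library left had 0 counts, so no fold is given. Without NVP2 replicate 1, IER5L stood at 8.47 and SMAD7 at 7.48, and ID3 stood at 6.12 without THZ531 replicate 2. CDK13 (1.93 ± 0.17) was higher, and CDK7 (0.94 ± 0.25, adjusted p = 0.0146) was too, but its call ended without THZ531 replicate 1 (0.083), NVP2 replicate 1 (0.146) or NVP2 replicate 2 (0.0543), with the NVP2 libraries summed (0.0864) and on the mitochondrial scale (0.0932). CDK12 (0.43, 0.02 to 0.84) and CDK9 (0.44, 0.04 to 0.83) were not called.

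Lower with THZ531 than with NVP2 were MIR3648-2 (−3.15 ± 0.60, or −3.77 without THZ531 replicate 1), SNORD3B-1 (−2.72 ± 0.76, adjusted p = 0.0214), CCDC77 (−2.30 ± 0.27), GNE (−1.77 ± 0.33) and TMEM238 (−1.67 ± 0.51, adjusted p = 0.0306). The call of SNORD3B-1 ended without THZ531 replicate 2 (0.115), NVP2 replicate 1 (0.0577) or 2 (0.0964), and it stood at −3.49 without THZ531 replicate 1. That of TMEM238 ended without THZ531 replicate 1 (0.149) or NVP2 replicate 1 (0.0979) or 2 (0.105). With the NVP2 libraries summed the values were 0.0687 for SNORD3B-1 and 0.0935 for TMEM238, by the DESeq2 Wald test 0.0555 for SNORD3B-1, and on the mitochondrial scale 0.124 for GNE and 0.277 for TMEM238. In all 2379 genes were higher and 684 lower (1888 and 266 by at least 2-fold), or 1683 and 36 on the mitochondrial scale, so 97.9% of calls were higher there against 77.7%. The split was 2142 and 424 without THZ531 replicate 2, 1565 and 207 without NVP2 replicate 1, and 1579 and 221 without NVP2 replicate 2.

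Held with an estimated correlation, whose p stands second, were TGF-beta and YAP targets (median 3.75; 8 of 13 higher, and 10 adjusted over the list alone, camera adjusted p = 2.83e-12 and 0.00133), receptor tyrosine kinase feedback (2.25; 11 of 15 higher and 1 lower, 11 and 1 adjusted over the list alone, camera adjusted p = 2.83e-12 and 0.0351) and survival and NF-kB targets (0.87; 10 of 17 higher and 1 lower, 11 and 1 adjusted over the list alone, camera adjusted p = 0.000134 and 0.0351). So were p53 targets (0.59, camera adjusted p = 0.00948), elongation genes (0.79, camera adjusted p = 1.9e-06) and the integrated stress response (0.96, camera adjusted p = 0.000531), each with an adjusted p = 0.0448 with an estimated correlation. SPRY2, which restrains receptor signalling, was higher by 5.48 ± 0.36, MCL1 by 3.25 ± 0.19 and CCNT1 by 2.91 ± 0.18. Immediate early genes had a median of 2.35 (17 of 21 higher, 17 and 1 adjusted over the list alone, camera adjusted p = 2.83e-12 and 0.121). DNA replication (−0.21, camera adjusted p = 0.0102; 0.06 on the mitochondrial scale), mitosis (−0.14, camera adjusted p = 0.0425; 0.18 on that scale) and the respiratory chain (−0.21, camera adjusted p = 0.0107; 0.13 on that scale) changed sign with the scale, with adjusted p = 0.675, 0.675 and 0.678 at an estimated correlation.

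THZ1 against NVP2 compares inhibition of CDK7 with that of CDK9. MYC was higher with THZ1 by 1.86 ± 0.28 (SE, n = 2 libraries per group, adjusted p = 0.00113). CCN2, a YAP target, was higher by 3.85 ± 0.52, the arginine- and serine-rich RSRP1 by 3.56 ± 0.34, RNF139, a ubiquitin ligase, by 3.54 ± 0.24, IER5L by 6.45 ± 0.57 and ID1 by 3.34 ± 0.71 (adjusted p = 0.0152). CDK13 was higher by 1.03 ± 0.17 (adjusted p = 0.00201); CDK12 (0.21, −0.20 to 0.62), CDK9 (0.17, −0.23 to 0.57) and CDK7 (0.79, 0.25 to 1.33) were not called. CDK13 lost its call without NVP2 replicate 2 (0.0774), and ID1 without NVP2 replicate 1 (0.182) or 2 (0.149) or THZ1 replicate 2 (0.124), or with the NVP2 libraries summed (0.139). When only the 2 groups were fitted, the calls of MYC (1.79, adjusted p = 0.0659), CCN2 (0.08) and CDK13 (0.126) ended, and on the mitochondrial scale that of CDK13 did (0.173). CCN2 stood at 4.48 and 2.67 without THZ1 replicates 1 and 2, and IER5L at 7.24 without NVP2 replicate 1 and 5.56 without THZ1 replicate 2.

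Lower with THZ1 than with NVP2 were the factor RUNX1 (−1.15 ± 0.30, adjusted p = 0.0478), the kinase PRKCE (−1.05 ± 0.27, adjusted p = 0.0438), PSRC1 (−1.03 ± 0.24, adjusted p = 0.0277), MLPH (−1.01 ± 0.21, adjusted p = 0.0108) and KLHL22 (−0.94 ± 0.24, adjusted p = 0.0411). All 5 calls ended when only the 2 groups were fitted (0.0687, 0.105, 0.154, 0.096 and 0.179 in that order), with the NVP2 libraries summed (0.208, 0.203, 0.157, 0.0769 and 0.207) and on the mitochondrial scale (0.56, 0.709, 0.736, 0.717 and 0.732). They also ended without NVP2 replicate 1 (0.209, 0.293, 0.209, 0.121 and 0.28 in that order) and without NVP2 replicate 2 (0.255, 0.183, 0.16, 0.0659 and 0.196). Without THZ1 replicate 1 the values were 0.0614 for RUNX1, 0.0636 for PRKCE and 0.13 for PSRC1, and without THZ1 replicate 2 0.361 for RUNX1, 0.31 for PRKCE, 0.146 for MLPH and 0.38 for KLHL22. In all 491 genes were higher and 34 lower (383 and 29 by at least 2-fold), or 184 and 12 on the mitochondrial scale and 203 and 11 with the NVP2 libraries summed. The split was 192 and 10 without NVP2 replicate 1, 186 and 9 without NVP2 replicate 2, 623 and 178 without THZ1 replicate 1, and 303 and 19 without THZ1 replicate 2. Without a filter it was 706 and 114, and with only the 2 groups fitted 55 and 3.

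TGF-beta and YAP targets were higher with THZ1 than with NVP2 (median 0.97; 5 of 13 higher, and 6 adjusted over the list alone, camera adjusted p = 2.2e-05, adjusted p = 0.0256 with an estimated correlation). Called at the preset correlation alone were immediate early genes (1.03, 7 higher, camera adjusted p = 5.15e-05, adjusted p = 0.449 with an estimated correlation), receptor tyrosine kinase feedback (0.88, 8 higher, camera adjusted p = 9.53e-09 and 0.0841), elongation genes (0.31, 6 higher, camera adjusted p = 2.2e-05 and 0.0841), the integrated stress response (0.55, 2 higher, camera adjusted p = 0.00113 and 0.0841), survival and NF-kB targets (0.39, 1 higher, camera adjusted p = 0.00842 and 0.0918) and heat shock (0.29, 1 higher, camera adjusted p = 0.00842 and 0.24). The second value of each pair is with an estimated correlation. Adjusted over the list alone these lists had 8, 8, 10, 6, 4 and 2 members higher, with 1 lower for immediate early and 1 for elongation genes. ERRFI1, which inhibits ERBB receptors, was higher by 1.8 ± 0.29 and CCNT1 by 1.59 ± 0.18, a call that ended when only the 2 groups were fitted (adjusted p = 0.054).

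Subtracting the HCC1954 response to THZ531 from that of SKBR3 asks where the lines differ. NFE2L2, which drives antioxidant genes, had a difference of −1.67 ± 0.24 (SE, n = 2 libraries per group, −2.17 to −1.16, adjusted p = 0.0473) and CERK, a ceramide kinase, −1.54 ± 0.23 (−2.03 to −1.06, adjusted p = 0.0473). MYC differed by 0.35 (−0.44 to 1.14) and CDK12 by −0.46 (−1.03 to 0.12), neither called; CDK13 stood at −0.20, CDK9 at −0.01 and CDK7 at 0.10. By edgeR 0 genes had a higher and 2 a lower response in SKBR3, with 987 at an unadjusted p under 0.05, while the DESeq2 Wald test called 42 higher and 10 lower, and edgeR without a filter 75 and 18. The calls of NFE2L2 and CERK ended with DESeq2 size factors (0.0518), when only these groups were fitted (0.263), without the NVP2 libraries (0.113) and on the mitochondrial scale. Leaving out either DMSO library of HCC1954, or any SKBR3 library, left 0 calls. Without HCC1954 THZ531 replicate 1, 1 other gene was called, and without replicate 2, 3 were. Immediate early genes had a median difference of 0.62 (camera adjusted p = 4.89e-07, adjusted p = 0.429 with an estimated correlation; 2 higher adjusted over the list alone).

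The same subtraction for sgMYC against unedited HCC1954 asks whether the MYC edit alters the response. MYC differed by −0.60 ± 0.37 (SE, n = 2 libraries per group, −1.39 to 0.19), and CDK12 by 0.25 (−0.32 to 0.83); CDK13 stood at −0.09, CDK9 at 0.27 and CDK7 at 0.46, none called. By edgeR 0 genes differed, with 536 at an unadjusted p under 0.05; the DESeq2 Wald test called 0, with 418 unadjusted. On simulated data 4-fold differences of responses were called for 45 of 66 genes and 2-fold ones for 4 of 67. Cytosolic ribosomal proteins had a median difference of −0.17, and 0.59 on the mitochondrial scale (camera adjusted p = 0.000241, adjusted p = 0.718 with an estimated correlation). Mitochondrially encoded mRNAs had −0.90 (camera adjusted p = 3.49e-06, adjusted p = 0.718 with an estimated correlation).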

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

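The tests of scaling and of the NVP2 libraries were chosen only after the results they concern were seen; the prediction on wrong labels and the tests of differing responses were written before.

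With TMM scaling 1226 genes were higher with THZ531 in HCC1954, among them MYC, and 784 in sgMYC cells, and counts are relative to each library. If a shrinking mRNA pool were behind such rises, scaling to the mitochondrially encoded mRNAs should remove most of the median rise in each pair of a THZ531 and a DMSO library. It removed 65.7% to 224% of a median rise of 0.76 in HCC1954 and −28.4% to 101% of one of 0.82 in sgMYC cells. These ranges decide nothing, and whether mitochondrial mRNA stayed constant was not measured, so a shrinking pool and a true rise of these mRNAs cannot be told apart.

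The 110 genes higher with THZ531 and lower with NVP2 and THZ1 include MYC and the homeobox gene DLX2. If the HCC1954 THZ531 libraries were wrongly labelled, the genes should show no rise in SKBR3, and 96.4% stood above 0 there, which argues against it. Mitochondrial scaling removed 52.2% to 178% of their median rise against DMSO, so there a shrinking pool and a true change cannot be told apart. It removed at most 33.6% of their median difference from THZ1 (2.34) or NVP2 (3.84) in any library pair. In both tests 90 of the 110 stayed called. The genes were chosen for these differences and scaling moved the median gene by −0.05 and 0.30, so this cannot test a shrinking pool. The different targets of the inhibitors stay open and were not tested.

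The NVP2 libraries were closer than any other pair. A single library sequenced again would give a chi-square near 1 per degree of freedom, and the pair gave 2.66, which argues against that. With a coefficient of variation of 3.88%, the pair could be a single RNA sample prepared again or a pair of very similar cultures; the labels do not say, and these cannot be told apart. Summed as 1 sample, the NVP2 libraries gave 3091 called genes against DMSO, in place of 4998.

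By edgeR the responses to THZ531 that differed between SKBR3 and HCC1954 were those of NFE2L2 (−1.67) and CERK (−1.54), against 52 genes by the DESeq2 Wald test and 93 by edgeR without a filter. Both calls ended with DESeq2 size factors (adjusted p = 0.0518), and leaving out a library ended them for 7 of the 8 libraries (0.0796 to 0.323). Median differences between these lines were 0.62 for immediate early genes, 0.26 for TGF-beta and YAP targets, 0.15 for heat shock genes, 0.37 for the integrated stress response and 0.37 for luminal markers; camera adjusted p values were 4.89e-07, 0.0203, 0.0443, 0.000127 and 0.0443, and 0.429, 0.149, 0.429, 0.101 and 0.429 with an estimated correlation. Between sgMYC and unedited HCC1954 the median differences were −0.17 for cytosolic ribosomal proteins, or 0.59 on the mitochondrial scale, and −0.90 for mitochondrially encoded mRNAs, neither of them called with an estimated correlation.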

How the results depend on the processing

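The settings without the NVP2 libraries, with these summed, and on the mitochondrial scale were chosen only after the results were seen.

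Counts of called genes that moved by more than 1.5 times follow; unless the construction is named, the cause was not tested. By the DESeq2 Wald test 185 genes differed between sgMYC and unedited cells in DMSO and 52 in response between SKBR3 and HCC1954. With DESeq2 size factors 0 differed in that response. Without a filter these 2 counts were 373 and 93, THZ1 against NVP2 gave 820 and the sgMYC difference in response 18. Fitting only the groups compared gave 1484 for THZ531 in HCC1954, 48 for sgMYC, 575 for THZ531 against THZ1 and 58 for THZ1 against NVP2. It gave 0 for the SKBR3 difference and raised NVP2 less, to 6496. Summing the NVP2 libraries, which leaves 1 sample assumed to vary like the others, gave 3091 for NVP2, 1876 for THZ531 against NVP2 and 214 for THZ1 against NVP2. Leaving NVP2 out gave 7 for sgMYC and 0 for the SKBR3 difference. On the mitochondrial scale the counts were 8827 for NVP2, 521 for THZ531 in sgMYC cells, 6 for sgMYC, 430, 1719 and 196 for THZ531 against THZ1, THZ531 against NVP2 and THZ1 against NVP2, and 1 for each difference in response; the 13 mRNAs used vary between replicates. The stricter filter moved no count of genes by that much.

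Leaving out 1 library, whose partner is then assumed to vary like the others, gave 1929 to 2710 genes for THZ531 in HCC1954, 2946 to 4032 for NVP2, 3436 to 4474 for THZ1, 1322 to 2068 for THZ531 in SKBR3 and 635 to 1320 in sgMYC cells. It gave 0 to 8 for sgMYC, 1081 to 2249 for THZ531 against THZ1, 1772 to 2566 for THZ531 against NVP2, 195 to 801 for THZ1 against NVP2, 0 to 3 for the SKBR3 difference and 0 to 0 for the sgMYC difference.

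The replicate numbers do not state a pairing. With them as a block, 131 genes differed between sgMYC and unedited cells (110 higher and 21 lower) and 42 in the SKBR3 difference (33 higher and 9 lower), and 11 and 3 lists were called for THZ1 against NVP2 and the SKBR3 difference. Deviations of the paired numbers correlated across genes between DMSO and THZ531 (0.668 in HCC1954, 0.509 in SKBR3, 0.471 in sgMYC cells) and by 0.216 between DMSO and THZ1 and 0.00719 between DMSO and NVP2.

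With an estimated correlation in place of the preset 0.01, 3 lists were called for NVP2, 1 for THZ1, 1 for THZ531 against THZ1, 6 for THZ531 against NVP2, 1 for THZ1 against NVP2 and 0 in each other comparison. By fry, a test of each list on its own, they numbered 15 for THZ1, 0 for THZ531 in sgMYC cells, 1 for sgMYC, and 0 for each difference in response.

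Requiring at least 2-fold, which keeps fewer genes by construction, THZ531 and NVP2 shared 51 higher and 991 lower genes with 92 higher then lower, THZ531 and THZ1 shared 106 higher with 42 higher then lower, and NVP2 and THZ1 shared 80 higher. HCC1954 and SKBR3 shared 248 and 795 with 0 opposite, and HCC1954 and sgMYC cells 214 and 773. Under the stricter filter the Spearman coefficient of length and change was −0.0684 for THZ531 in HCC1954 and reversed to 0.00135 for THZ1.

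Of 301 values of single genes tried, 267 were called, and no called one changed sign except on the mitochondrial scale, by whose construction values shift. There THZ531 in HCC1954 gave ATP5F1B −0.39, CLK1 −0.052, CPSF1 −0.36, CPSF6 −0.23, FANCA −0.46, MT-CO2 −0.18, MT-ND3 −0.36, PHGDH −0.10, RPL18 −0.38 and, uncalled, CDK7 −1.01. NVP2 gave CYC1 −0.70, PHGDH −0.50, PSAT1 −0.40, RPL3 −0.52 and RPL8 −0.65; THZ1 gave RPL3 −0.081 and UQCRC1 −0.025; THZ531 in SKBR3 gave ATP5F1B −0.075 and CDK7 −0.64. For sgMYC it gave CDK12 0.083, CDK13 0.15 and CDK7 0.020, for the SKBR3 difference CDK13 0.072 and CDK9 0.16, and for the sgMYC difference CDK13 0.67 and MYC 0.22.

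Uncalled kinases near 0 also changed sign elsewhere. With DESeq2 size factors, the Wald test and only the groups compared, CDK13 stood at 0.049, 0.047 and 0.0029 for THZ531 in HCC1954 and at 0.0078, 0.0067 and 0.010 for sgMYC. With the first 2 of these, CDK12 stood at 0.0051 and 0.0043 for THZ531 in sgMYC cells. With the stricter filter CDK9 stood at 0.022 for the SKBR3 difference. Leaving out 1 library gave CDK13 −0.11 to 0.075 and CDK7 −0.25 to 0.35 for THZ531 in HCC1954, CDK7 −0.45 to 0.19 for THZ1, CDK7 −0.22 to 0.39 for THZ531 in SKBR3, and CDK12 −0.17 to 0.14 and CDK13 −0.19 to 0.019 in sgMYC cells. It gave CDK12 −0.30 to 0.017, CDK13 −0.14 to 0.065 and CDK7 −0.45 to 0.14 for sgMYC against unedited cells, CDK7 −0.10 to 0.46 for THZ531 against THZ1, CDK7 −0.24 to 0.37 and CDK9 −0.13 to 0.15 for the SKBR3 difference, and CDK13 −0.19 to 0.028 for the sgMYC difference.

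Named calls lost were 2 with DESeq2 size factors, 1 by the Wald test, 30 with only the groups compared and 52 without some library. They were 6 of 174 without the NVP2 libraries, 12 of 93 with these summed, and 67 plus 17 reversed on the mitochondrial scale. None was lost with no filter or the stricter one. On simulated data with the depths of these libraries and the same spread in every group, 2 of 67 changes of 1.5-fold were called. The part of depth in this was not tested.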

Other observations

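The groups of genes below and their tests were chosen only after the results were seen.

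Zinc finger genes named ZNF, many of them repressors of transposable elements, were lower than other coding genes with every inhibitor. Of 427 such genes, 226 were lower with THZ531 in HCC1954 (52.9%, against 13.5% of 12619 other coding genes), 318 with NVP2 (74.5% against 22.6%) and 317 with THZ1 (74.2% against 20.6%). With THZ531, 193 were lower in SKBR3 (45.2% against 12.1%) and 129 in sgMYC cells (30.2% against 9.16%). Median log2 changes were −1.19, −1.97, −1.85, −1.01 and −0.75, and camera with an estimated correlation gave adjusted p = 0.00196 for each of the inhibitors in HCC1954, 0.00347 for SKBR3 and 0.00676 for sgMYC cells. ZNF526 was among the largest falls with THZ531 in HCC1954 (−3.38 ± 0.27) and with THZ1 (−5.07 ± 0.31). Higher members numbered 7, 2, 0, 6 and 6. Reads of these paralogs can be shared, which was not tested.

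Calls were also counted by gene type, and differences between types or inhibitors were not tested. Of 87 sense intronic transcripts, 20 were higher and 4 lower with THZ531 in HCC1954, 13 and 5 in SKBR3, and 17 and 1 in sgMYC cells, against 1 and 12 with NVP2 and 6 and 7 with THZ1. Of 662 antisense genes, 46 were higher and 40 lower with THZ531 in HCC1954, 6 and 76 with NVP2, and 17 and 47 with THZ1, and of 13046 protein coding genes 977 and 1927, 1404 and 3176, and 1808 and 2916. Reads of the sense intronic transcripts cannot be separated from those of the host genes' introns, and these counts are for TMM scaling alone.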
